A study of Mus musculus with 6 samples.

How the data were processed

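RNA from 6 samples of mouse epiblast stem cells was hybridised to Affymetrix MoGene 1.0 ST arrays, 1 array per sample, with 3 Dicer fx/fx controls and 3 Dicer-deleted samples from experiments 18, 19 and 20. Per the submitters' processing notes the arrays were processed with RMA and Affymetrix Expression Console 1.2, and per the file headers the probe sets carry an mm9 annotation. The authors deposited each array in 2 forms. The first is a linear intensity, from 27.2 to 25736, which the header calls raw but whose arrays have nearly equal medians. The second is a log2 value centred on the median of the same probe set over the 6 arrays; the deposited log2 value equals the log2 of the deposited intensity minus that median to within 2.31e-06. The deposited series table holds the same centred values, with a largest difference of 0, so the planned comparison of source tables moved nothing and is void. The program that centred the values is not given in the sources used here. RMA had already corrected background and normalized the arrays against each other, so a general shift in RNA content between groups cannot be seen, and no scanner values or detection calls were used.

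From these values the log2 level was restored as the centred value plus the probe set median. Of 28856 probe sets, 22439 named 1 gene symbol, 2815 several and 3602 none. Probe sets that named several genes or none were left out, with 9 more whose 1 symbol had several gene identifiers; tested apart, these 6426 gave 0 past the threshold and 375 at an unadjusted p under 0.05. A gene was represented by its probe set with the highest mean over all 6 arrays, which concerned 1305 genes with more than 1. This gave 20193 genes. Symbols were updated through Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, used for names alone: 19486 genes matched, 707 kept the symbol of the array and 2175 had a changed symbol. No coordinates are given because that assembly differs from that of the array annotation. A planned test of genes with seed matches in their 3' UTRs was not run because it needs sequences, and these are not analysed here.

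Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, no intensity trend, not robust), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The design, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The 29 lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists, and again with an estimated correlation and with fry; counts adjusted over the list alone use the members' own p-values. Named genes were Dicer1 and Bcl2l11, then up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold with the same direction in all 3 experiments, with free places filled by the smallest unadjusted p, and from each list up to 4 members past the threshold or else the 2 with the smallest unadjusted p. Some genes that this rule names are not reported here. Clone names, small RNAs, receptor segments and pseudogenes were to be passed over among the 16, which concerned 0 genes. A list's median was also placed among the medians of 10000 random lists of the same size matched on mean level in 50 bins.

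The experiment numbers pair the samples, because the labels describe each experiment as holding both a control and a deleted sample kept side by side. In the data, the deviations from the group means of the 2 arrays of an experiment correlated across genes with r = 0.83 in experiment 18, 0.61 in experiment 19 and 0.80 in experiment 20. The fit without the experiment stayed the main one, as planned, and the fit with it as a block is given beside results it changed. No 2 arrays held identical values. Alternatives were the block, a filter keeping genes at or above the median level, eBayes with trend and robust settings, quantile normalization again, centring of arrays on their medians, the mean of all probe sets of a gene, array weights, other thresholds, other list tests, lists without shared genes, and leaving out each array and each experiment.

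The scripts were tested on simulated data made from the levels, experiment effects and residual spread of the 20193 genes, with 200 genes changed in each of 5 runs. For the comparison of deleted with control cells, 78.4% of genes changed by 1.7 log2 units and 21.8% of those changed by 0.6 were recovered without the block, and 88% and 41.2% with it, with an average of 0 and 3.2 false calls per run. A list of 28 genes shifted by 0.3 passed an unadjusted p of 0.05 in 5 of 5 runs with either fit. The simulated residuals were independent between genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.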

Results

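Gene expression was measured in mouse epiblast stem cells (EpiSCs), the primed pluripotent cells of the post-implantation epiblast, with and without Dicer, the ribonuclease that cuts microRNA precursors into mature microRNAs. The cells carried floxed Dicer alleles and were grown with 20 ng/ml Activin and 12 ng/ml bFGF. Deletion was started with 0.3 µM 4-OH-tamoxifen for 3 days, the cells were kept 2 more days without it, and RNA was taken on day 5. Controls of the same line were plated and divided alongside and had no tamoxifen, so exposure to the drug and to the recombinase went with deletion in every sample. The numbers in the array names place the controls before the deleted samples, so array order may have gone with deletion as well. There were 3 independent deletion experiments, numbered 18, 19 and 20, each with 1 control and 1 deleted sample, which gave 6 Affymetrix mouse gene arrays and 20193 genes tested. The median array intensity lay between 247.7 and 260.1 in all 6 arrays. The 25th percentile was 92.52 to 93.58 in controls and 89.48 to 90.39 in deleted samples. The number of arrays limits the precision. Unless said otherwise, values are log2 differences of deleted minus control with the SE of the limma fit, n = 3 arrays per group. This SE is that of the fit without the experiment, so it also holds differences in baseline between experiments. For a gene whose baseline differed it can be wider than the spread of the changes within experiments.

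The deleted gene was examined first. Dicer1 (Entrez 192119) fell in all 3 experiments, from a mean log2 level of 10.97 ± 0.11 in controls to 9.23 ± 0.11 in deleted cells (SD, n = 3). The difference of -1.74 ± 0.09 left 29.9% of the control signal. The array intensity went from 1836 to 601.6 in experiment 18, from 2079 to 553.1 in experiment 19 and from 2098 to 645.4 in experiment 20, so every sample followed its label. Which probes of this probe set lie in the deleted part of the gene is not given in the sources used here. Bcl2l11 (Entrez 12125), which encodes the pro-apoptotic protein BIM that the study's title names, had a mean log2 level of 10.49 ± 0.31 in controls and 11.09 ± 0.13 in deleted cells (SD, n = 3). Its signal was 1.56-fold higher with deletion in experiment 18, 1.25-fold in experiment 19 and 1.8-fold in experiment 20, a mean difference of 0.60 ± 0.17. Dicer1 passed the test over all genes with a limma adjusted p of 0.045, and Bcl2l11 did not, with an adjusted p of 0.824. With the experiment as a block the adjusted p was 0.067 for Dicer1, which ended its call, and 0.159 for Bcl2l11. Dicer1 also lost its call when any 1 of the 6 arrays was left out, with an adjusted p of 0.226 without control 18, 0.729 without control 19, 0.397 without control 20, 0.705 without deleted 18, 0.449 without deleted 19 and 0.265 without deleted 20. Its difference stayed between -1.80 and -1.68. In a two-sided exact permutation test each of the 2 genes gave p = 0.1, the smallest that 3 arrays against 3 can give. That test takes the arrays as unpaired.

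**Figure D1:**
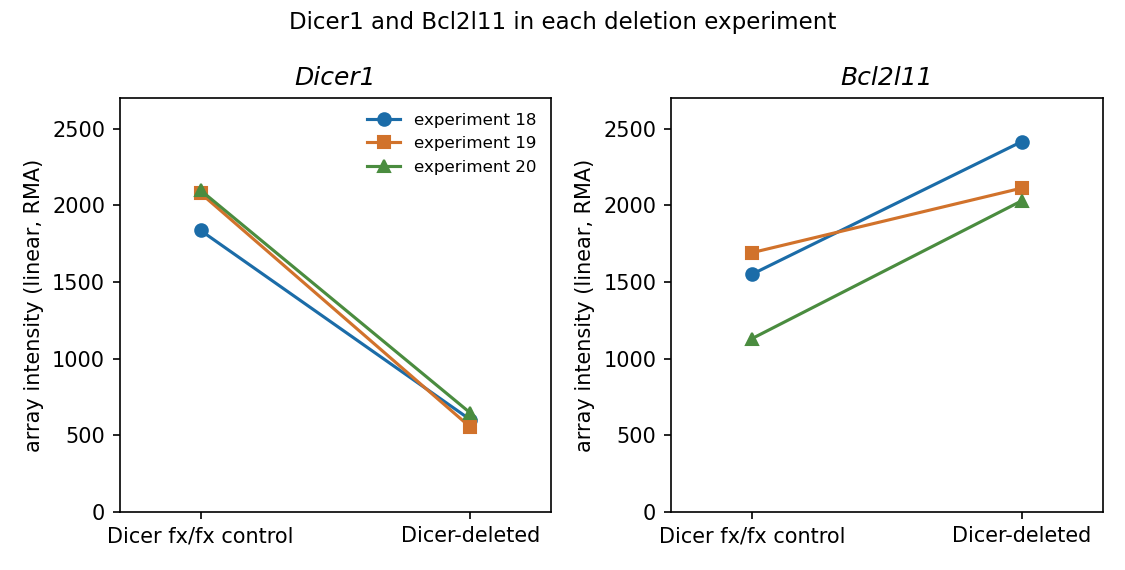
Array intensity (linear scale, RMA) of Dicer1 (left) and Bcl2l11 (right) on each of the 6 arrays; a line joins the control and the deleted sample of 1 experiment. Dicer1 lay between 553.1 and 645.4 in deleted samples against 1836 to 2098 in controls, and Bcl2l11 was higher in the deleted sample of each experiment.

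The comparison of deleted with control cells over all genes asks which transcripts depend on mature microRNAs in primed pluripotent cells. Dicer1 was the 1 gene of 20193 that fell, and 0 genes rose at an adjusted p under 0.05. Below the threshold, differences recurred between experiments: 3072 genes were higher and 5705 lower with deletion in all 3, which is 43.5% of genes where independent signs would give 25%. The excess of lower genes came from dim genes: at or above the median level 2355 genes were higher and 2186 lower in all 3. The median change was -0.04 among the dimmest 5049 genes and -0.07 among the next 5048. Several genes named below as lower are dim, among them Tex101, Afp, Sox7, Pmaip1, Esx1 and Oas3, with mean log2 levels of 6.64 to 7.21. How much of their small falls belongs to this general shift was not tested. Of the genes that differed at least 1.5-fold in mean and in the same direction in all 3 experiments, 181 were higher and 20 were lower in deleted cells. None of the 8 genes with the smallest unadjusted p on the higher side passed. The first of them were Dock5, a guanine nucleotide exchange factor for Rac (0.62 ± 0.06, adjusted p = 0.403), Skida1 (1.01 ± 0.13), the glycosyltransferase gene Mgat4a (0.91 ± 0.12) and Tmem123 (0.58 ± 0.08). The next 4 were the lipid phosphatase gene Mtmr4 (0.50 ± 0.07), Astn1 (0.49 ± 0.07), the annexin gene Anxa6 (0.44 ± 0.06) and the profilin gene Pfn2 (0.41 ± 0.06). On the lower side, after Dicer1, stood Abhd14a (-0.44 ± 0.06), the proteasome assembly gene Psmg3 (-0.36 ± 0.06) and Ptpn11, which encodes the phosphatase SHP2 (-0.46 ± 0.07). They were followed by Rdh8 (-0.36 ± 0.06), the imprinted gene Phlda2 (-0.60 ± 0.10), Gpat4 (-0.31 ± 0.05) and the aspartate aminotransferase gene Got1 (-0.40 ± 0.07). All but Dock5 among these 15 had an adjusted p of 0.824. At an unadjusted p under 0.05 limma counted 449 genes higher and 762 lower, 1211 where chance gives 1010, and with the experiment as a block 1623 higher and 1828 lower, of which 0 passed. Among genes at or above the median level the balance turned, with 267 higher and 130 lower, 397 where chance gives 505, and 1173 higher and 732 lower with the block. Without experiment 20, the fit with the block gave 314 genes that rose and 74 that fell; without experiment 18 or without experiment 19 it gave 0.

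Groups of genes were compared through 29 lists chosen before the data were examined. As a group, the genes reported elsewhere as targets of the miR-290, miR-302 and miR-17 families, which dominate the microRNAs of pluripotent cells, rose in deleted cells. Of its 28 measured members 27 had a higher mean and 19 were higher in all 3 experiments, while 0 were lower in all 3; the median difference was 0.27. The median was 0.15 in experiment 18, 0.29 in experiment 19 and 0.42 in experiment 20. The members with the smallest unadjusted p were the survival kinase gene Akt1 (0.48 ± 0.11) and Bcl2l11, neither of which passed over all genes, and 0 members passed when p was adjusted over the list alone. With the experiment as a block, 12 of the 28 rose when adjusted over the list alone. These 12, named after their values were seen, were the transcription factor gene Irf2 (0.84), Bcl2l11 (0.60), the initiator caspase gene Casp8 (0.50), Akt1 (0.48), the methyl-CpG binding gene Mbd2 (0.47), Fndc3a (0.45), the cell cycle regulators E2f1 (0.38), Ccnd1 (0.29) and Rbl1 (0.25), Cfl2 (0.34), Arid4b (0.28) and the BMP receptor gene Bmpr2 (0.26). The list test, camera with a preset correlation, gave an adjusted p of 4.7e-10, and the list kept its call without each array and without each experiment, with an adjusted p of at most 4.84e-05. With an estimated correlation the adjusted p was 0.227, and the list includes Bcl2l11, the gene that the study's title names, which makes it not fully independent of the study.

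**Figure D2:**
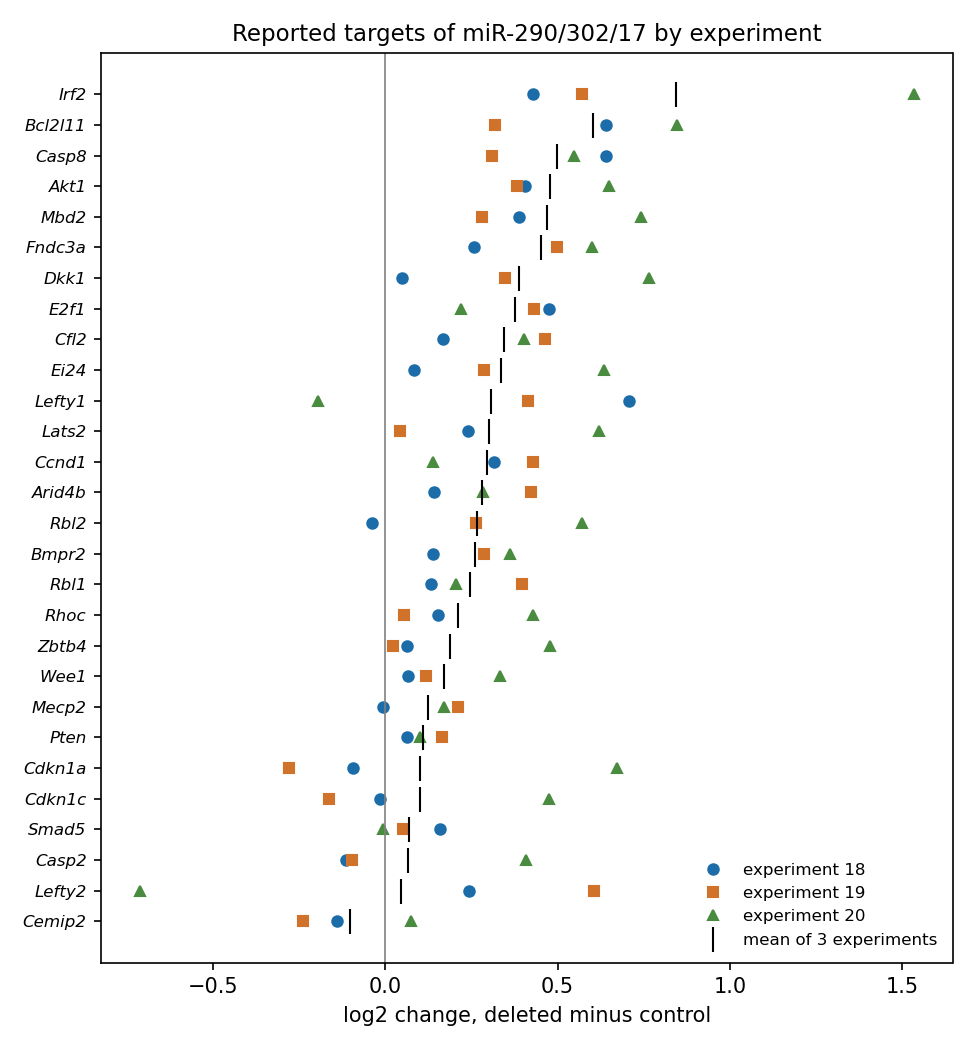
Log2 change (deleted minus control, x axis) of each of the 28 measured members of the list of reported miR-290, miR-302 and miR-17 targets (y axis) in experiments 18, 19 and 20, with a bar at the mean of the 3. Most points lie to the right of 0, and 19 genes are above 0 in all 3 experiments.

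In total 8 of the 29 lists were called higher and 0 lower with the preset correlation, and 0 either way with an estimated one. The calls other than that of the microRNA targets were smaller. The glycolysis list had 19 of 25 members with a higher mean and a median of 0.08 (adjusted p = 0.0031). It was led by the pyruvate dehydrogenase kinase gene Pdk3 (0.54 ± 0.14) and the enolase gene Eno3 (0.62 ± 0.29). Caspases and death receptors had 13 of 18 with a higher mean and a median of 0.08 (adjusted p = 0.016). Casp8 was at 0.50 ± 0.32 and Aifm1 at 0.24 ± 0.11. With the experiment as a block the SE was 0.083 for Casp8 and 0.078 for Aifm1. Interferon response genes had 20 of 30 with a higher mean and a median of 0.13 (adjusted p = 0.016). The members with the smallest unadjusted p differed in opposite directions, the antiviral gene Ifit2 by 0.59 ± 0.23 and Oas3 by -0.18 ± 0.07. Cell cycle inhibitors had 13 of 15 with a higher mean and a median of 0.17 (adjusted p = 0.016). The Hippo kinase gene Lats1 was at 0.28 ± 0.13 and the mitotic inhibitor gene Wee1 at 0.17 ± 0.08. Lysosome and autophagy genes had 17 of 31 with a higher mean and a median of 0.01 (adjusted p = 0.021). Lamp2 was at 0.66 ± 0.17. In Nodal and Activin signalling, which sustains the primed state, 15 of 26 had a higher mean and the median was 0.06 (adjusted p = 0.021). Smad2 was at 0.31 ± 0.09. Fibroblast and mesenchymal markers had 15 of 24 with a higher mean and a median of 0.07 (adjusted p = 0.022). Zeb2, a repressor of epithelial genes, was at 0.87 ± 0.26, and the collagen gene Col5a2 at -0.20 ± 0.07, with Col1a1 at -0.06 and Col1a2 at 0.03. None of these members passed over all genes, and 0 passed when adjusted over the list alone. With the experiment as a block, the counts that rose over the list alone were 2 in glycolysis, 1 among caspases, 3 in the interferon list, 0 among cell cycle inhibitors, 2 in the lysosome list, 3 in the Nodal list and 5 among mesenchymal markers. The last included fibronectin, Fn1 (0.68).

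None of these 7 calls held with an estimated correlation, where the adjusted p was 0.679 for glycolysis, 0.402 for caspases and for Nodal signalling, 0.68 for the interferon list, 0.45 for cell cycle inhibitors, 0.72 for the lysosome list and 0.599 for mesenchymal markers. With the few degrees of freedom of that setting, a lost call does not by itself show that members are correlated. For Nodal signalling the estimated correlation was -0.026, below the preset 0.01, yet the unadjusted p of camera went from 0.0051 to 0.035. When quantile normalization was applied again, 3 lists were called higher (microRNA targets, caspases and interferon response) and 1 lower (integrated stress response). Among genes at or above the median level 3 were called higher (microRNA targets, mesenchymal markers and naive pluripotency) and 1 lower (integrated stress response). With array weights 4 were called higher (microRNA targets, glycolysis, Nodal signalling and primed pluripotency). Without genes held by more than 1 list 6 were called higher, and the calls of caspases (0.0509), cell cycle inhibitors (0.138) and Nodal signalling (0.0969) were lost. Leaving out 1 array of a pair lets the baseline of its experiment enter the difference. Several calls were lost without 1 array of experiment 20. Without its control the adjusted p was 0.102 for caspases, 0.208 for cell cycle inhibitors, 0.134 for mesenchymal markers, 0.238 for glycolysis, 0.529 for the lysosome list and 0.067 for the interferon list. Without its deleted array it was 0.105 for the first 3, 0.075 for the lysosome list and 0.795 for the interferon list. Calls were also lost without control 18 (interferon 0.179, Nodal 0.179), control 19 (lysosome 0.053), deleted 18 (glycolysis 0.107, lysosome 0.422) and deleted 19 (Nodal 0.083). The Nodal call was lost without experiment 18 (0.0845) or experiment 19 (0.11) as well.

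The cell death genes outside the caspases pointed both ways. Of 12 measured pro-apoptotic BCL2 family genes, 4 had a higher mean and 6 were lower in all 3 experiments (median -0.12, adjusted p = 0.358). Bcl2l11 was higher, as given above, while Pmaip1, which encodes NOXA, was at -0.23 ± 0.07. With the experiment as a block and adjusted over the list alone, Bcl2l11 rose and 4 members fell, Bid (-0.38), Bok (-0.29), Pmaip1 and Hrk (-0.21); without the block 0 did. Of 9 pro-survival genes 4 had a higher mean (median -0.02, adjusted p = 0.841). The caspase inhibitor gene Xiap was at 0.34 ± 0.11 and rose over the list alone with the block, and Birc5 was at -0.26 ± 0.14. The p53 targets gave an adjusted p of 0.847 with 12 of 30 members at a higher mean, Aen at -0.40 ± 0.12 and Pmaip1 leading. Without experiment 20 the p53 list was called lower, with an adjusted p of 0.0019; with all arrays and an estimated correlation its adjusted p was 0.9946. Proliferation genes were not called (12 of 32 with a higher mean, median -0.02, adjusted p = 0.841). Aurka, a mitotic kinase gene, was at -0.32 ± 0.10 and cyclin D3, Ccnd3, at 0.32 ± 0.11.

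Pluripotency genes as groups did not pass. General pluripotency genes had 8 of 21 members with a higher mean (median -0.04, adjusted p = 0.992). Dppa4 was at -0.22 ± 0.10 and Esrp1 at -0.27 ± 0.17, and Pou5f1 was at -0.03 and Sox2 at 0.15. Among naive pluripotency genes 9 of 21 had a higher mean (median -0.04, adjusted p = 0.4). The LIF pathway members Il6st, the gp130 receptor subunit gene (0.81 ± 0.16), and Stat3 (0.61 ± 0.14) were higher in all 3 experiments. With Lifr (0.43) they rose over the list alone with the block. Among genes at or above the median level the naive list was called higher, with an adjusted p of 0.03, or 0.7005 with an estimated correlation. Primed pluripotency genes had 16 of 25 with a higher mean (median 0.04, adjusted p = 0.082), with Dnmt3a at 0.13 ± 0.08. With the block the primed list was called higher (adjusted p = 0.01, or 0.599 with an estimated correlation), and Cdh2 (0.62) and the primitive streak gene T (1.48) rose over the list alone. It was also called higher without control 19 (0.038), control 20 (0.0061), deleted 18 (0.029) or experiment 20 (0.00113).

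The lineage lists were not called. The controls differed between experiments at some of their genes, picked by hand. Control intensity in experiments 18, 19 and 20 was 186.9, 215.7 and 3673 for Mixl1 and 161.3, 206.1 and 1110 for Sox17. For Hand1 it was 230.7, 236.7 and 242. Over all genes, control 20 correlated with controls 18 and 19 at r = 0.971 and 0.977, against 0.992 between those. The SE of the main fit holds such differences (1.405 for Mixl1), so a list left uncalled may still have changed. Mesoderm and primitive streak genes had 7 of 22 members with a higher mean (adjusted p = 0.697), with Evx1 at -0.18 ± 0.09 and Wnt3 at -0.22 ± 0.11. Endoderm genes had 11 of 22 (0.992), with Sox7 at -0.20 ± 0.06 and Afp at -0.17 ± 0.06; with the block 2 members rose over the list alone. Neural ectoderm genes had 12 of 21 with a higher mean (0.232), with Ncam1 at 0.39 ± 0.17. With the block the neural list was called higher (adjusted p = 0.04, or 0.47 with an estimated correlation), and the radial glia gene Fabp7 (0.81) rose over the list alone. Trophectoderm genes had 5 of 20 with a higher mean (0.437), with Esx1 at -0.23 ± 0.06 and Tead4 at -0.14 ± 0.08. Germ cell genes had 5 of 21 (0.287), with Nanos3 at -0.19 ± 0.06 and Tex101 at -0.14 ± 0.06. The test fry, which does not compare a list with other genes, called the germ cell list lower (adjusted p = 0.049). However, the list median of -0.05 lay at percentile 46.53 of random lists matched on mean level. In experiments 18, 19 and 20 the percentile was 20.82, 78.88 and 29.67. The fall was thus typical of genes at this level, which argues against a change particular to germ cell genes. Epithelial genes had 7 of 24 with a higher mean (median -0.14, adjusted p = 0.397), with Ovol1 at -0.28 ± 0.09. With the block 3 members fell over the list alone, Cldn7 (-0.40), Crb3 (-0.40) and Spint2 (-0.28). WNT signalling had 10 of 22 with a higher mean (0.858), with Wnt3a at -0.24 ± 0.06 and Wnt3 next. BMP signalling had 10 of 18 with a higher mean (0.992), with Bambi at -0.24 ± 0.07 and Smad1 at -0.23 ± 0.10. With the block 2 members rose over the list alone, Bmp2 (0.58) and Bmpr2 (0.26), and 3 fell, Id1 (-0.67), Id2 (-0.35) and Msx2 (-0.24).

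Beyond Dicer1, 1 other gene of the microRNA machinery passed when adjusted over its list alone. In the list of microRNA pathway proteins 15 of 21 members had a higher mean (median 0.03, adjusted p = 0.118). Adjusted over the list alone, Dicer1 fell and Tnrc6a, which encodes a GW182 partner of Argonaute, rose (0.64 ± 0.12). With the experiment as a block Ago1 (0.64), Tnrc6b (0.69) and Ago3 (0.27) rose as well. With the block the list was called higher, with an adjusted p of 0.031, and 0.47 with an estimated correlation. It was also called higher without control 19 (0.038) and without genes held by more than 1 list (0.0042). The second of these settings takes the deleted gene itself out of the list, since the let-7 list holds Dicer1 too. MicroRNA host transcripts had 8 of 13 with a higher mean (median 0.17, adjusted p = 0.574), with H19 at -0.40 ± 0.22 and AU018091 at -0.14 ± 0.08. With the block this list was called higher (0.01, or 0.47 with an estimated correlation). Its highest members were the precursor probe sets of the miR-302 cluster, among them Mir367 (0.77) and Mir302c (0.67). They belong to 1 cluster and are not taken as independent, and which transcripts they detect was not tested. H19 fell over the list alone. The list of reported let-7 targets had 18 of 29 with a higher mean (median 0.05, adjusted p = 0.251), and its 1 member past the threshold was Dicer1. With the block 2 members rose over the list alone. It was called higher without experiment 20 (adjusted p = 0.047); with all arrays and an estimated correlation its adjusted p was 0.7204.

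Of the remaining lists, integrated stress response genes had 22 of 25 members with a lower mean and a median of -0.19 (adjusted p = 0.212), with the endoplasmic reticulum stress gene Herpud1 at -0.59 ± 0.17 and Cebpb at -0.30 ± 0.12. The list was called lower with the experiment as a block (adjusted p = 0.01, or 0.663 with an estimated correlation), without experiment 18 (4.06e-09), without control 18 (1.3e-08) and without deleted 19 (0.012). Its median was 0.09 in experiment 18, -0.27 in experiment 19 and -0.45 in experiment 20. DNA methylation genes had 10 of 17 with a higher mean (median 0.07, adjusted p = 0.096), with the hydroxylase gene Tet1 at 0.39 ± 0.18 and Dnmt3l at -0.19 ± 0.11; without control 19 the list was called higher (0.046), with all arrays and an estimated correlation its adjusted p was 0.5987, and with the block 3 members rose over the list alone. Histone genes had 15 of 21 with a higher mean (median 0.05, adjusted p = 0.186), with H2ax at -0.55 ± 0.18 and H2bc4 at 0.35 ± 0.32. The histone list was called higher without control 20 (0.00044), deleted 18 (0.015) or deleted 19 (0.046); with all arrays and an estimated correlation of 0.5684 its adjusted p was 0.8946. The median, mean and test differed in sign in 8 lists, none of them called: pro-survival genes, p53 targets, proliferation genes, general and naive pluripotency, WNT, BMP and endoderm.

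**Figure D3:**
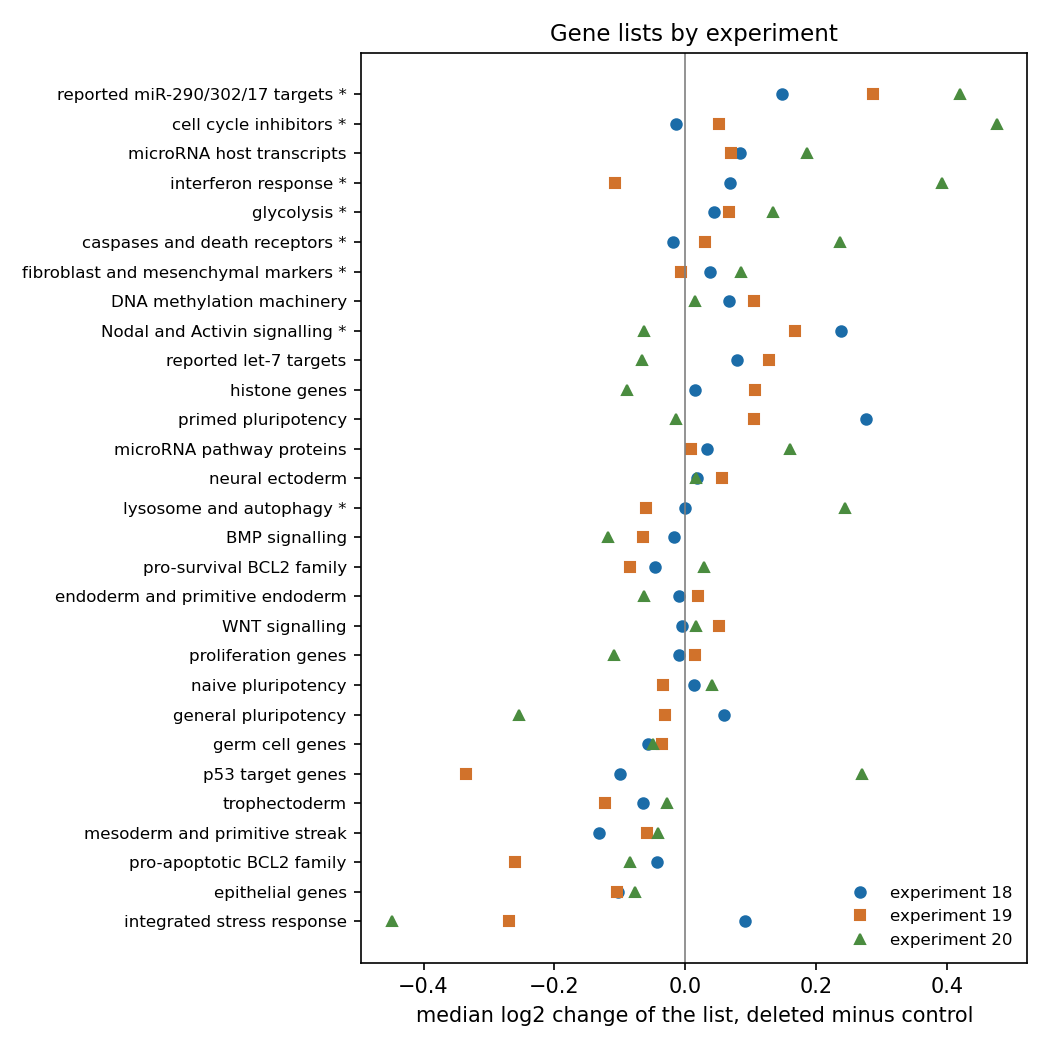
Median log2 change (deleted minus control, x axis) of each of the 29 lists (y axis; an asterisk marks the 8 called with a preset correlation) in experiments 18, 19 and 20. The list of microRNA targets lies at 0.15, 0.29 and 0.42, while p53 targets lie at -0.10, -0.34 and 0.27.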

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

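The fits that combine 2 settings, and the target list without Bcl2l11, were chosen after the data were seen. The count of genes lower with deletion, 1 in the main fit, was 0 with the replicate block and 0 with trend and robust eBayes, where the Dicer1 difference stayed at -1.74 with an adjusted p of 0.067 and 0.107. Leaving out arrays or experiments gave 0 to 74 genes lower and 0 to 314 higher, with Dicer1 between -1.81 and -1.66. The cause was not tested; leaving out arrays also lowers the number of samples. Both counts kept their values, 0 and 1, under renewed quantile normalization, median centring, the mean of probe sets, array weights, the filter on dim genes, at least 1.5-fold and an adjusted p under 0.1. The block with an adjusted p under 0.1 also gave 0 and 1, and the block with the filter on dim genes gave 0 and 1 at 0.05 but 58 higher and 3 lower at 0.1. Bcl2l11 was higher and short of the threshold under every alternative run. Of the 1278 values of the 66 named genes other than Dicer1, 1260 kept direction and side, 17 passed the threshold without experiment 20 under the block, and 1 turned: H2bc4 was at -0.019 without the deleted array of experiment 20, and its values with an array or experiment left out ran up to 0.561. The 8 lists called higher became 12 with the replicate block, 3 with the filter on dim genes, 3 with renewed quantile normalization, 4 with array weights, 6 without genes of more than 1 list, 0 with an estimated correlation, 0 with fry, 5 with block and filter, 0 with block and estimated correlation and 0 with filter and estimated correlation. Leaving out arrays or experiments gave 3 to 10. Lists called lower, 0 in the main fit, were 1 with the block, 1 with the filter, 1 with renewed quantile normalization, 1 with fry (germ cell genes), 1 with block and filter, and 0 to 2 with arrays or experiments left out. The microRNA target list had an adjusted p of 0.227 with an estimated correlation, 0.234 with fry, 0.47 with block and estimated correlation and 0.468 with filter and estimated correlation, and stayed called in the other 21 of 25 alternatives, including the one without Bcl2l11. The causes of these moves were not tested, apart from the lower number of genes and samples that the filter and the omissions bring. With the block and without experiment 20, general pluripotency (0.0403) and DNA methylation (0.0276) were called higher and epithelial genes lower (0.0322). With all arrays, no block and an estimated correlation, the adjusted p of these lists was 0.9946, 0.5987 and 0.8614. Alternatives for the seed matches were not run for want of sequences, the second source table held the same values, and trend and robust settings do not enter camera or fry here; without background values, how far dim genes stand above background is unknown.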

Other observations

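The genes named in the first 2 paragraphs and the tests of the weighed patterns, apart from the splits of arrays and the count of tamoxifen-treated arrays with intact Dicer, were chosen after the values were seen. In the fit with the experiment as a block, some of the genes with the smallest p after Dicer1 act in signalling and guidance. They were picked by hand from a longer ranking in which other genes stand between them. Rgs2, a regulator of G protein signalling, was higher by 1.15, 1.09 and 0.97 on the log2 scale in experiments 18, 19 and 20 (adjusted p = 0.137). The axon guidance ligand genes Slit2 and Sema3e were higher by 1.93, 1.41 and 1.53 and by 0.73, 0.91 and 0.93, and the ephrin receptor gene Epha4 by 0.75, 0.62 and 0.95. The Hedgehog receptor gene Ptch1 was higher by 0.63, 0.81 and 0.65, the interferon-inducible gene Ifitm3 by 0.97, 0.81 and 1.04, and Taf9b by 1.11, 1.84 and 1.42. The adjusted p of these 6 was 0.138, so none passed. With experiment 20 left out and the block kept, 314 genes rose and 74 fell, and 262 and 55 of them had the same direction in experiment 20, where 42.5% of all genes were higher.

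Some pluripotency and Nodal genes, picked by hand, were lower in experiment 20 than in the others, as were the medians of the general pluripotency list (0.06, -0.03 and -0.25 in experiments 18, 19 and 20), the primed list (0.28, 0.11 and -0.01) and the Nodal list (0.24, 0.17 and -0.06), but not of the naive list (0.01, -0.03 and 0.04). Nanog was at 0.28 and -0.03 in experiments 18 and 19 and at -1.24 in experiment 20, Foxd3 at 0.80 and 0.92 against -0.86, Nodal at 0.54 and 0.28 against -0.54, and the Nodal co-receptor gene Tdgf1 at 0.71 and 0.59 against -0.72, while T was higher in all 3, by 1.54, 2.15 and 0.75. The p53 targets had medians of -0.10, -0.34 and 0.27; relative to the mean of all arrays, the list lay at 0.075, 0.28 and -0.16 in the controls of experiments 18, 19 and 20 and at -0.03, -0.05 and 0.01 in the deleted samples. Across genes, which are not independent replicates, changes correlated with r = 0.50 between experiments 18 and 19, 0.35 between 18 and 20 and 0.26 between 19 and 20. Differences between experiments were not tested, each having 1 sample per group.

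Other splits of the 6 arrays into 3 and 3 bear on how far chance can be excluded. The real split gave 1 gene past the threshold and the highest of the others 0, so 1 of the 10 splits gave as many. It gave 8 lists and the highest of the others 10, and 5 of the 10 splits gave as many. With 10 splits the share is never under 0.1, too few to exclude chance. Since the numbers pair the samples, the closest comparison is with the 3 other splits that part all pairs, which gave 0 genes each and 6, 6 and 9 lists; the remaining 6 keep 2 pairs whole and so set experiments against each other. The list of microRNA targets had an unadjusted p of 1.62e-11 in the real split, the smallest of the 10, and of 0.911, 0.000264 and 1.23e-08 in those 3. On the side without control 18, the list was higher in the real split and in the first and second of those 3 splits, but lower in the third. Each of these keeps 2 of the 3 pairs as they were or reverses 2, so a real rise would leave part of itself there and the values do not decide.

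The higher level of reported miR-290, miR-302 and miR-17 targets could come from the level at which these genes are expressed, since the median change of all genes was -0.04 and that of genes at or above the median level 0.00. Against this, the list median lay at percentile 100 of 10000 random lists matched on mean level. The list also kept its call among genes at or above the median level. Against an origin in experiment 20 alone, its median lay at or above percentile 99.96 in both experiment 18 and experiment 19. Such percentiles take the members as independent, so the percentiles alone do not settle either explanation. The p53 list, not called in the main fit, lay at percentiles 0.01, 0 and 100 in experiments 18, 19 and 20. Exposure to tamoxifen or the recombinase cannot be told apart from the loss of Dicer, since 0 arrays came from cells that had tamoxifen and kept Dicer. A rise of direct targets after loss of microRNAs stays open as a hypothesis, not separated from indirect effects.

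For the other lists called higher, the same explanations give different answers. The fibroblast list lay at percentile 99.97 of lists matched on level. It kept its call among genes at or above the median level (adjusted p = 0.0024, or 0.5273 with an estimated correlation). This argues against level as the cause, though the filtered test covers only 12 of its 24 members. Extreme percentiles also occurred in lists not called in the main fit: 99.97 for microRNA host transcripts and 0 for epithelial and integrated stress response genes. The glycolysis, caspase, interferon and cell cycle inhibitor lists lay at or above percentile 99.32. They lost their calls among genes at or above the median level (0.1079, 0.1348, 0.1859 and 0.1079), where fewer genes are tested. The glycolysis list kept all its 25 members there, so its loss did not come from fewer members. The caspase list kept 13 of 18, the interferon list 12 of 30 and the cell cycle inhibitors 11 of 15. With the experiment as a block as well, glycolysis kept its call there (0.0489) and the others were each at 0.0586. Level therefore stays open for these lists. The lysosome list at percentile 74.58 is consistent with it, and the Nodal list at 97.06 leaves it open. Experiment 20 may account for the caspase, interferon, cell cycle inhibitor, fibroblast and lysosome calls: without it their adjusted p was 0.106 to 0.488, and without experiment 18 or 19 at most 0.0319. With the block and without experiment 20 it ran from 0.0523 for the fibroblast list to 0.959 for the lysosome list. The interferon list is less clear, with matched percentiles of 99.85, 8.49 and 100 in experiments 18, 19 and 20. Its member Ifit2 was at 0.851, 0.832 and 0.102. For the glycolysis list an origin in experiment 20 stays open: its call held without experiment 20 (0.0051, or 0.0107 with the block), but its matched percentiles in experiments 18 and 19 were 79.27 and 91.29. Experiment 20 does not account for the Nodal call, which held without it (0.000364) and was lost without experiment 18 (0.0845) or 19 (0.11). Tamoxifen and loss of Dicer stay confounded here too, so no biological cause was separated. Both tests replaced earlier ones whose results had been seen. The test of level was first that of the glycolysis list among genes at or above the median level, then the percentile alone, and now takes both. The test of experiment 20 was first the matched percentile in experiments 18 and 19, where 0 of 6 lists, glycolysis among them, passed 95 in both; by that test experiment 20 may account for the glycolysis call as well, so the 2 tests disagree on it. For the p53 targets, 3 tests were run and dropped. Dicer1 was at -1.701 in experiment 20, which argues against swapped arrays, and the list lay at percentile 100 of lists matched on level there. The third asked whether the control of experiment 20 alone set the opposite direction; the deleted array lay 0.048 above the higher of the other 2, which met the bound set against it, but it was dropped since the controls carry most of the spread.

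That transcripts of the effector complex of microRNAs are under the control of microRNAs themselves is a hypothesis. It was not tested here, since seed matches were not examined. The 7 genes Ago1 to Ago4 and Tnrc6a to Tnrc6c had a median change of 0.27, and 6 were higher in all 3 experiments; camera gave an unadjusted p of 2.3e-05 with a preset correlation and 0.0986 with the estimated one of 0.522. Their median lay at percentile 99.82 of sets matched on level, but the set was picked after several were looked at, among them X-linked genes and 75 axon guidance genes (unadjusted p = 0.00785), so neither the p nor the percentile is corrected for that search and level as a cause stays open. It lay at percentiles 99.89, 98.46 and 99.02 in experiments 18, 19 and 20. Its median change was 0.292, 0.194 and 0.329, and 6 of the 7 genes changed more in experiment 20 than in experiment 18, so an origin mainly in experiment 20 stays open too. Exposure to tamoxifen is confounded with deletion for these genes as well.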
